A study of Mus musculus with 48 samples.

How the data were processed

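RNA was measured in 48 livers of C57BL/6 mice, 6 per genotype in each of 4 conditions. Per the labels' protocols, livers were flash frozen, total RNA was purified with a TRIzol Plus kit, and libraries were made with NEBNext Ultra Directional reagents, which keep the strand of the transcript. The authors deposited 4 tables, 1 per condition, each with 12 libraries and 54532 features named by Ensembl identifier and symbol. The deposited unit is a signal, normalized counts: gene counts divided by 1 factor per library, with each table normalized on its own. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 and the builds mm10 and GRCm38, which are names for 1 mouse assembly. Their versions and settings, the annotation, and how strand and reads matching several places were counted are not given in the sources used here. Reads shared by near-identical copies, and by overlapping or antisense genes, can therefore have been split or lost, which bears on the Mup family, histone genes and the overlapping genes named in the results.

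The low values of each library were whole multiples of a step of 0.6335 to 1.3864, and with that step 99.973% to 100% of the values of a library came out as whole reads, within 0.05 reads. In 4 libraries (fasted knockout 4, refed controls 2 and 6, refed knockout 5) the step is close to 1, so whole values say less there. Size factors computed again from the recovered reads by DESeq2's median ratio, multiplied by these steps, gave 1 to within 1e-08. Recovered totals were 41 M to 83.8 M reads per library, which sets the counting error. No pair of libraries of 1 group agreed within sampling noise, so all 48 were counted. The columns carried genotype and replicate number as in the labels, and 0 value columns were left without a sample. Identifiers were matched to GENCODE M21 on GRCm38 for positions and gene types, and 54409 of 54532 features (99.77%) matched. Where several features carry 1 symbol (105 features beyond the first of their symbol), each was tested on its own, so that Ddit3 counts as 2 members of its list.

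Calculations were made in R 4.3.3. Each condition was tested within its own table by limma 3.58.1 (limma-trend, robust empirical Bayes) on log2(normalized count + 1), knockout minus control, for genes with a mean of at least 10 over the 12 libraries, with Benjamini-Hochberg adjusted p under 0.05. The pseudocount of 1 understates the change of low genes. The mean of the 4 conditions and the difference of the genotype effect between diets and between feeding states were contrasts of a model with 8 or 4 group means, in which the scale of each table cancels. Foxk1 and Foxk2 were compared by exact two-sided permutation of 6 against 6 livers, adjusted over 8 tests. A set of 46 gene lists (31 pathways, 15 marker lists of cell types) was tested by camera with a preset correlation of 0.01 between genes where at least 5 members were measured, and again with a correlation estimated for each list; no list passed with the estimated correlation in any condition. The permutation of 4 conditions together relabelled livers within each table.

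The tests, samples, gene lists, rule for named genes and alternatives were set before the data were examined. The rule named Foxk1, Foxk2, Cpt1a and Ccl2; in each comparison the 8 genes that rose and the 8 that fell with the largest log2 change among those past the threshold with a mean of at least 50 in each table and a symbol that is not a predicted-gene name; 5 of each sign in each interaction; and the 4 members with the smallest p of each list described. Which lists to describe, the 6 with the smallest camera p in each condition, was decided after the results were seen, and cholangiocyte markers were added to these. Some results the rule names are not reported here. The test of list scores, the mean log2 value of the members per liver permuted between genotypes, was also added after seeing the data.

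Alternatives were pseudocounts of 0.5 and 10, no filter or a mean of at least 50, rescaling by TMM, ppm of the library's total, weighted libraries, the replicate number as a block, each library left out in turn, and count models on the recovered reads, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 (Wald test). In simulated data drawn from each table's means and spread with 200 changed genes, the test within a condition recovered 26.9% to 46.3% of genes changed 1.5-fold, 82.1% to 85.1% of those changed 2-fold and 95.5% to 98.5% of those changed 4-fold, and 3.4% to 7.4% of calls over all comparisons were false. The mean of the 4 conditions recovered 86.6%, 97% and 97% over 18075 genes. These draws held 200 changed genes and no correlation between genes. The recovery and false-call rates may therefore be too favourable for the real livers, where other splits called up to 83 genes after refeeding. Other draws of the samples were 100 per result. Tables of different conditions were normalized separately, so levels across them were set side by side as ppm without a test.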

Results

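Gene expression was measured by RNA sequencing in 48 livers of C57BL/6 mice, 12 in each of 4 conditions. In each condition 6 livers carried 1 floxed Foxk1 allele with Alb-Cre and served as controls, and 6 carried 2 floxed alleles with Alb-Cre and are called knockouts here. Alb-Cre expresses the Cre recombinase in hepatocytes, so both genotypes carried Cre and the comparison is between heterozygous and homozygous floxed livers. Mice aged 18 weeks had eaten a normal diet (ND, 15 kcal% fat) or a diet labelled CDAHFD (62 kcal% fat), which the labels list under models of NASH, a fatty and inflamed state of the liver, for 12 weeks. Mice aged 10 weeks had been fasted for 24 hours, or fasted for 24 hours and then refed for 2 hours. Libraries held 41 M to 83.8 M counted reads, with a median of 51.2 M. Values are normalized counts, log2 changes are knockout minus control on the log2(normalized count + 1) scale with their standard error (SE). Each group had n = 6 livers. The labels do not state how animals were assigned or whether each liver came from a separate animal, so p-values measure the spread between these samples.

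Foxk1, a forkhead transcription factor (ENSMUSG00000056493, GRCm38 chromosome 5, 142401497 to 142462011, plus strand), was measured first in every liver as a check of the genotype labels. After fasting it fell from 658 ± 61.7 normalized counts in controls to 509 ± 19.5 in knockouts (SD, n = 6), which was 22.6% lower. In normalized counts the groups did not overlap, with controls at 585.8 to 731 and knockouts at 495.9 to 545.7. For these values the exact two-sided permutation p was 0.00216, the smallest that 6 livers against 6 can give. It was 0.0173 after Benjamini-Hochberg adjustment over 8 tests. As ppm of each library's counts the groups did overlap, with controls at 9.89 to 15.7 and knockouts at 10.2 to 11.1. After refeeding it was 592 ± 82 in controls and 492 ± 50.1 in knockouts (17% lower, exact p = 0.0281, adjusted p = 0.113). On the normal diet the values were 530 ± 95.3 and 435 ± 58.6 (17.8% lower, exact p = 0.0584, adjusted p = 0.156). On CDAHFD they were 810 ± 194 and 682 ± 68.2 (15.8% lower, exact p = 0.19, adjusted p = 0.364). In all 4 conditions the 6 knockout livers lay below the control mean, and over the 4 conditions Foxk1 fell by 0.28 ± 0.06 log2 units (limma adjusted p = 0.00351). The exons removed from the floxed allele are not given in the sources used here, so transcripts that lack them may still be counted, as are those of cells other than hepatocytes. Foxk2, the closest relative of Foxk1, did not separate by genotype in any condition (exact p = 0.227 on ND, 0.34 on CDAHFD, 0.372 after fasting and 0.913 after refeeding). The refed Foxk1 difference depended on single livers. Its exact p no longer lay under 0.05 without control 3 (-0.208 log2 units), knockout 1, knockout 2 or knockout 3. On ND the exact p came to lie under 0.05 without control 4, control 5 or knockout 1 (-0.333). On CDAHFD the difference of -0.222 was -0.127 without control 2.

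**Figure D1:**
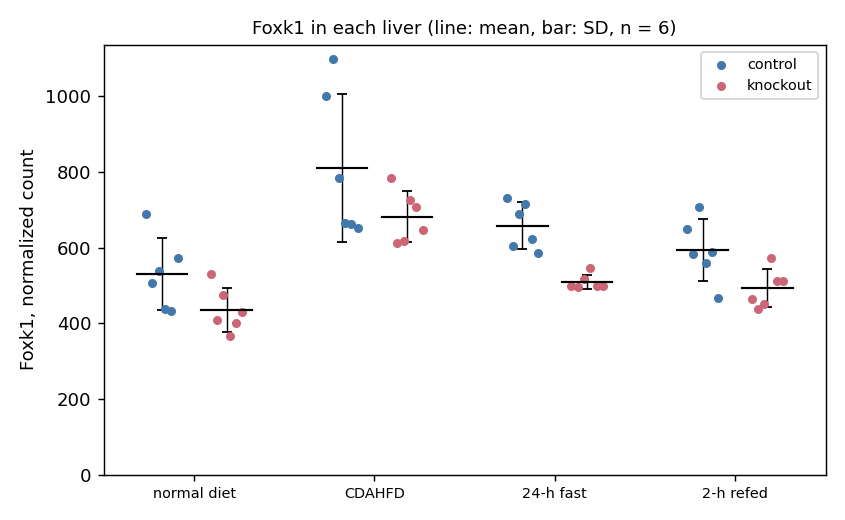
Foxk1 normalized counts in each of the 48 livers (vertical axis) by condition and genotype (horizontal axis); points are livers and bars mark the group mean with its SD, n = 6 per group. After fasting the knockouts, at 495.9 to 545.7, all lie below the controls, at 585.8 to 731, and in the other 3 conditions the ranges overlap.

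On the normal diet, 1 gene passed the test. Lgals1, which encodes the carbohydrate-binding protein galectin-1, rose from 780 ± 89.2 to 1280 ± 152 normalized counts (SD, n = 6), a log2 change of 0.72 ± 0.10 (limma adjusted p = 0.0379). It was higher in 6 of 6 knockouts than the control mean (ENSMUSG00000068220, chromosome 15, 78926725 to 78930465). In a test of each gene list against all other genes, genes of lipid handling differed in direction. Of 23 PPAR alpha targets outside oxidation 18 were higher in knockouts (camera adjusted p = 1.17e-05, adjusted p = 0.562 with an estimated correlation). Of 24 genes of fatty acid and triglyceride synthesis 21 were lower (camera adjusted p = 0.000137, adjusted p = 0.562 with an estimated correlation). Among the PPAR alpha targets, Cd36, a fatty acid transporter, differed by 0.64 ± 0.18, Cidec, a lipid droplet protein, by 0.64 ± 0.21, Slc22a5, a carnitine transporter, by 0.51 ± 0.19, and Fabp2 by 0.35 ± 0.13. Among the synthesis genes, Elovl6, a fatty acid elongase, differed by -0.73 ± 0.23, and Acaca, which makes malonyl-CoA, by -0.29 ± 0.11, while Mogat1, which makes diacylglycerol, differed by 0.99 ± 0.31. In both lists 0 members passed the test over all genes or adjusted over the list alone. Cpt1a, which admits fatty acids to mitochondria, was at 11300 ± 1650 in controls and 12700 ± 1370 in knockouts (0.16 ± 0.10). Ccl2, a chemokine that attracts monocytes, was at 19.3 ± 11.1 and 21.5 ± 15.1 (0.12 ± 0.48). Neither passed (limma adjusted p = 0.996 for both).

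Marker lists of liver cell types also passed camera on the normal diet, at its preset correlation alone. Of 15 hepatocyte markers 13 were lower (camera adjusted p = 0.00205, adjusted p = 0.709 with an estimated correlation). In this list Trf, the iron carrier transferrin, fell by 0.53 ± 0.09 when adjusted over the list alone but not over all genes (adjusted p = 0.0983). Alb, which encodes albumin, differed by -0.31 ± 0.11, Ttr by -0.29 ± 0.11 and Apoc3 by -0.27 ± 0.10. Of 15 stellate cell and fibroblast markers 13 were higher (camera adjusted p = 0.00257, adjusted p = 0.709 with an estimated correlation). Ngfr was at 0.55 ± 0.23, Tmem56 at 0.35 ± 0.13, Pdgfrb at 0.34 ± 0.21 and Dcn at 0.19 ± 0.14. Of 17 endothelial markers 15 were lower (camera adjusted p = 0.0103, adjusted p = 0.709 with an estimated correlation). Dnase1l3 was at -0.19 ± 0.10 and Fcgr2b at -0.18 ± 0.09. Of 18 heat shock genes, which encode protein-folding chaperones, 16 were higher (camera adjusted p = 0.00205, adjusted p = 0.709 with an estimated correlation). Hspa1b was at 0.71 ± 0.51, Hspa8 at 0.33 ± 0.19, Dnaja1 at 0.29 ± 0.12 and Hspd1 at 0.14 ± 0.09. The stellate, endothelial and heat shock lists had 0 members past the test over all genes or adjusted over the list alone. Beside these lists, features overlapping ribosomal RNA genes took 0.310% ± 0.05 of the reads in controls and 0.495% ± 0.113 in knockouts (SD, n = 6, exact permutation p = 0.00649, 0.156 adjusted over 24 library measures). The 10 most abundant genes took 15.6% ± 0.8 of the reads in ND controls and 14.7% ± 0.6 in ND knockouts (exact p = 0.0411, adjusted p = 0.299). In all, 12 of 40 tested lists passed the camera test with its preset correlation, 7 higher and 5 lower, and 0 with an estimated correlation.

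Of the 19099 genes tested on ND, 892 had an unadjusted p under 0.05, against 955 that chance would give. The single call was lost without control 2, 4 or 5 or without knockout 1, 2, 5 or 6 (0 genes each), became 2 genes without control 6 and 3 without control 3. Other tools called 1 (edgeR) or 24 genes (DESeq2, 16 up and 8 down).

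On CDAHFD, 25 genes rose and 0 fell in knockouts. Among genes with a mean of at least 50, most of those with the largest changes were pseudogenes of the Mup family, copies in the chromosome 4 cluster of genes for the major urinary proteins, which the liver secretes. Mup-ps14 rose from 40.4 ± 12.5 to 309 ± 147 normalized counts (SD, n = 6), a log2 change of 2.78 ± 0.35 (limma adjusted p = 0.00798). Mup-ps16 rose from 159 ± 25.5 to 937 ± 455, a change of 2.39 ± 0.32 (adjusted p = 0.00895). Mup-ps12 (2.65 ± 0.35), Mup-ps3 (2.40 ± 0.37), Mup-ps10 (2.33 ± 0.34), Mup-ps11 (2.32 ± 0.38) and Mup-ps8 (2.24 ± 0.38) rose as well. Mup copies are close to identical in sequence, so reads of one can be counted for another and the level of each is uncertain. Fam19a2, which encodes a small secreted protein (ENSMUSG00000044071, chromosome 10, 123263996 to 123741204), rose from 68.9 ± 29.5 to 436 ± 173 (2.68 ± 0.30, adjusted p = 0.00264). In all 8 of these genes the 6 knockouts lay above the 6 controls.

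Among the gene lists on CDAHFD, 28 of 29 interferon response genes were higher in knockouts (camera adjusted p = 1.68e-10, adjusted p = 0.675 with an estimated correlation). Of these 0 passed over all genes. Adjusted over the list alone 2 rose, Ifi27 by 0.61 ± 0.13 and Usp18 by 0.63 ± 0.17, while Iigp1 was at 0.38 ± 0.13 and Stat2 at 0.25 ± 0.08. Of 28 cell cycle genes 27 were lower (camera adjusted p = 2.98e-10, adjusted p = 0.675 with an estimated correlation). Over all genes 0 passed, and 5 fell when adjusted over the list alone, among them the mitosis genes Plk1 (-0.80 ± 0.24) and Prc1 (-0.72 ± 0.21), the proliferation marker Mki67 (-0.62 ± 0.19) and the topoisomerase Top2a (-0.57 ± 0.19). Of 24 genes of cholesterol synthesis and uptake 24 were higher (camera adjusted p = 8.13e-06, adjusted p = 0.675 with an estimated correlation). Over all genes 0 passed, and 1 did when adjusted over the list alone, Mvd (0.58 ± 0.13), beside Sc5d (0.42 ± 0.16), Fdps (0.37 ± 0.16) and Fdft1 (0.35 ± 0.12). Of 27 unfolded protein response genes 25 were higher (camera adjusted p = 1.77e-05, adjusted p = 0.675 with an estimated correlation). Derl3, which acts in the degradation of misfolded proteins, passed only when adjusted over the list alone (2.05 ± 0.39, adjusted p = 0.0733 over all genes), and Sesn2 was at 0.42 ± 0.20, Pdia4 at 0.35 ± 0.18 and Xbp1 at 0.22 ± 0.08.

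Markers of scarring and inflammation were lower in CDAHFD knockouts as lists by camera's preset correlation alone, with 0 members past the test over all genes or adjusted over the list alone. They were 17 of 18 markers of monocyte-derived macrophages (camera adjusted p = 8.8e-06, adjusted p = 0.675 with an estimated correlation). Chil3 was at -0.99 ± 0.28, Msr1 at -0.33 ± 0.12, Cd68 at -0.30 ± 0.16 and Csf1r at -0.28 ± 0.10. They were also 32 of 33 genes of fibrosis and extracellular matrix (camera adjusted p = 2.62e-05, adjusted p = 0.675 with an estimated correlation). Ctgf was at -0.57 ± 0.17, Mmp13 at -0.38 ± 0.19, Loxl2 at -0.26 ± 0.13 and Col14a1 at -0.17 ± 0.07. Beside them, 13 of 13 cholangiocyte markers were lower (camera adjusted p = 0.000217, adjusted p = 0.675 with an estimated correlation). These 3 differences rest in part on knockout 3. Without it the mean log2 difference of the list went from -0.319 to -0.175 for macrophages, from -0.24 to -0.106 for fibrosis and from -0.54 to -0.3 for cholangiocytes. Ccl2 was at 383 ± 83.2 in controls and 337 ± 129 in knockouts (-0.25 ± 0.24). Cpt1a was at 17100 ± 1990 and 20300 ± 3690 (0.24 ± 0.13, limma adjusted p = 0.674). Neither passed the test. In all, 18 of 43 lists passed with the preset correlation, 9 in each direction, and 0 with an estimated one.

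Of 21405 genes tested on CDAHFD, 1709 had an unadjusted p under 0.05, against 1070 by chance. DESeq2 called 147 genes (122 up, 25 down). The count was 10 without control 3, control 5 or knockout 6, 11 without control 4 or knockout 2, 13 without control 2, 14 without knockout 1, 15 without knockout 3, 41 without knockout 4 and 44 without control 6.

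After the 24-hour fast, 0 genes passed the test in limma, with 893 of 19054 genes at an unadjusted p under 0.05, against 953 by chance, and a smallest adjusted p of 0.451. edgeR called 0 and DESeq2 11 (7 up, 4 down). With the replicate number as a block 1707 genes had an unadjusted p under 0.05, and with weighted libraries 1546 did. In both settings 0 genes passed, and neither was checked under other splits. The main count therefore does not show that a genotype difference was absent. The lists with the smallest camera p were antigen presentation, fatty acid oxidation and genes higher in male liver, followed by cholesterol synthesis. Of 36 fatty acid oxidation genes 29 were lower in knockouts (camera adjusted p = 5.69e-05, adjusted p = 0.588 with an estimated correlation). Acsl1, which activates long-chain fatty acids, was at -0.24 ± 0.13, Acadvl at -0.23 ± 0.10, Hadha at -0.23 ± 0.12 and Etfa at -0.18 ± 0.09. Cpt1a of the same list went the other way. It was at 32700 ± 1890 in controls and 36500 ± 1270 in knockouts (SD, n = 6). The change was 0.16 ± 0.08 and did not pass (limma adjusted p = 0.976). Its groups did not overlap in normalized counts, but as ppm they did (547 to 737 in controls, 730 to 833 in knockouts). Ccl2 was below the filter on low values after fasting (2.79 ± 3.02 and 4.36 ± 3.51) and after refeeding (9.11 ± 6.62 and 7.12 ± 2.55). Of 24 cholesterol genes 23 were lower (camera adjusted p = 0.000726, adjusted p = 0.601 with an estimated correlation). Cyp51 was at -0.76 ± 0.52, Fdft1 at -0.46 ± 0.34, Pmvk at -0.45 ± 0.22 and Tm7sf2 at -0.25 ± 0.14. Of 11 genes of MHC class II antigen presentation 11 were higher (camera adjusted p = 5.69e-05, adjusted p = 0.545 with an estimated correlation). Cd74, the invariant chain, was at 0.69 ± 0.23, H2-DMb1 at 0.63 ± 0.32, H2-Eb1 at 0.55 ± 0.26 and Ctss at 0.42 ± 0.15.

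Also after the fast, 17 of 19 genes that are higher in male than in female liver were lower in knockouts (camera adjusted p = 5.69e-05, adjusted p = 0.545 with an estimated correlation). Elovl3 was at -1.24 ± 0.53, Cyp2d9 at -0.76 ± 0.25, Mup3 at -0.64 ± 0.22 and Ugt2b38 at -0.40 ± 0.15. Of 22 bile acid genes 18 were lower (camera adjusted p = 0.00246, adjusted p = 0.377 with an estimated correlation). Slc10a1, the bile acid importer, was at -0.34 ± 0.13 and Baat, which conjugates bile acids, at -0.31 ± 0.12, while the transporters Slco1a4 (0.62 ± 0.22) and Abcc4 (0.28 ± 0.14) were higher. Of 26 unfolded protein response genes 26 were higher (camera adjusted p = 0.000794, adjusted p = 0.545 with an estimated correlation). Psat1, an enzyme of serine synthesis, was at 1.14 ± 0.41, Chac1, which breaks down glutathione, at 1.12 ± 0.39, Ddit3 at 0.56 ± 0.29 and Dnajb9 at 0.36 ± 0.19. In these 6 lists 0 members passed over all genes or adjusted over the list alone. In all, 21 of 40 lists passed with the preset correlation, 12 higher and 9 lower, and 0 with an estimated one. On simulated data built from these fasted libraries with 18907 genes, the test recovered 26.9% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 95.5% of those changed 4-fold.

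After 2 hours of refeeding, 25 genes rose and 11 fell in knockouts. Osbpl3, which encodes an oxysterol-binding protein (ENSMUSG00000029822, chromosome 6, 50293330 to 50456201), rose from 122 ± 39.3 to 450 ± 218 normalized counts (SD, n = 6), a log2 change of 1.79 ± 0.31 (limma adjusted p = 0.0383). Chac1 rose from 32.2 ± 14.7 to 94 ± 28.1 (1.60 ± 0.30, adjusted p = 0.0383), and Adgrg2, an adhesion G protein-coupled receptor, from 56.9 ± 11.9 to 139 ± 27.5 (1.28 ± 0.18, adjusted p = 0.00385). Cyp39a1, an oxysterol hydroxylase of bile acid synthesis (ENSMUSG00000023963, chromosome 17, 43667425 to 43751431), fell from 1220 ± 246 to 486 ± 131 (-1.35 ± 0.20, adjusted p = 0.0112). G0s2, an inhibitor of the triglyceride lipase that empties lipid droplets, fell from 6460 ± 1180 to 3870 ± 854 (-0.74 ± 0.14, adjusted p = 0.0383). In the other conditions G0s2 was higher in knockouts, at 0.96 ± 0.53 on ND, 0.55 ± 0.20 on CDAHFD and 0.19 ± 0.37 after fasting, and Chac1 was lower on ND (-0.99 ± 0.47), none of which passed.

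Mup pseudogenes again were among the genes with the largest rises after refeeding, at a mean of at least 50. Mup-ps16 rose from 248 ± 78.3 to 805 ± 94.9 (1.74 ± 0.16, limma adjusted p = 0.000137), with Mup-ps12 at 2.16 ± 0.32, Mup-ps14 at 1.81 ± 0.25, Mup-ps10 at 1.64 ± 0.18 and Mup-ps2 at 1.52 ± 0.18. Further genes fell. The translation repressor gene Eif4ebp3 went from 16600 ± 3710 to 8490 ± 1990 (-0.97 ± 0.16, adjusted p = 0.0268) and its upstream neighbour Ankhd1 from 15900 ± 3110 to 8770 ± 1710 (-0.86 ± 0.14, adjusted p = 0.0171). Also lower were the tight junction gene Cldn14 (-0.71 ± 0.13), Gse1 (-0.59 ± 0.11) and the DNA replication gene Gins2 (-0.58 ± 0.11), all 3 at an adjusted p of 0.0383. Gse1 and Gins2 overlap by 2758 bases on opposite strands, and Gse1 also shares its strand with an overlapping predicted gene. G0s2 lies within Lamb3 on the opposite strand, and Ankhd1 overlaps a processed pseudogene, so with the strand setting of the counting not given their levels are uncertain. Adgrg2 overlaps an antisense transcript, with the same limit. Osbpl3 missed the threshold with no filter on low values and G0s2 with weighted libraries. Cldn14, Gse1 and Gins2 missed it when scaled to ppm of each library's total. With the replicate number as a block, Osbpl3, G0s2, Gse1 and Gins2 missed it. Cpt1a was at 22100 ± 3780 and 22700 ± 7360 (-0.01 ± 0.19, adjusted p = 0.996). Cd36, chosen after its values were seen, rose from 2180 ± 384 to 4890 ± 868 (1.17 ± 0.13, adjusted p = 0.000485).

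Of 26 unfolded protein response genes 23 were higher after refeeding (camera adjusted p = 6.78e-05, adjusted p = 0.615 with an estimated correlation). Chac1 passed over all genes. Adjusted over the list alone 5 rose and 1 fell, with Derl3 at 2.18 ± 0.47, Asns, which makes asparagine, at 1.28 ± 0.37 and Xbp1, a transcription factor of this response, at -0.33 ± 0.09. Pericentral hepatocyte genes, active around the central vein, were higher in 16 of 20 cases (camera adjusted p = 0.00022, adjusted p = 0.615 with an estimated correlation). Over all genes 0 passed, and 1, Ahr (0.48 ± 0.12), did when adjusted over the list alone, beside Cyp1a2 at 1.10 ± 0.34, Slc13a3 at 0.57 ± 0.19 and Aldh1a1 at 0.51 ± 0.18. Of 23 genes of xenobiotic metabolism, which share Cyp1a2 and Aldh1a1 with that list, 16 were higher (camera adjusted p = 0.00044, adjusted p = 0.615 with an estimated correlation). Cyp3a25 was at 0.41 ± 0.12 and Aldh1a7 at 0.40 ± 0.13. Of 11 MHC class II genes 11 were higher (camera adjusted p = 0.00044, adjusted p = 0.615 with an estimated correlation). H2-Aa was at 1.02 ± 0.53, Cd74 at 0.70 ± 0.43, Cd86 at 0.58 ± 0.18 and Ctss at 0.37 ± 0.20. The xenobiotic and MHC class II lists had 0 members past the test over all genes or adjusted over the list alone.

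Markers of Kupffer cells, the resident macrophages of the liver, were higher in 8 of 9 cases in refed knockouts (camera adjusted p = 0.000467, adjusted p = 0.615 with an estimated correlation). Over all genes 0 passed, and 5 rose when adjusted over the list alone, among them Cd5l (0.75 ± 0.22), Folr2 (0.68 ± 0.25), Timd4 (0.62 ± 0.22) and Vsig4 (0.36 ± 0.14). Of 17 endothelial markers 17 were lower (camera adjusted p = 0.000978, adjusted p = 0.615 with an estimated correlation). Stab1 was at -0.27 ± 0.12, Flt1 at -0.26 ± 0.10, Eng at -0.23 ± 0.08 and Vwf at -0.20 ± 0.12, and 0 passed over all genes or adjusted over the list alone. Beside these lists, the 10 most abundant genes took 15.1% ± 1 of the reads in controls and 13.8% ± 0.6 in knockouts (SD, n = 6, exact permutation p = 0.0152, 0.182 adjusted over 24 library measures). In all, 12 of 39 lists passed with the preset correlation, 11 higher and 1 lower, and 0 with an estimated one. Of 19093 genes tested, 2063 had an unadjusted p under 0.05, against 955 by chance. DESeq2 called 230 genes (164 up, 66 down). The count of 36 was 13 without control 3, 14 without control 1, 15 without control 6 or knockout 4, 18 without knockout 2, 19 without control 4, 21 without control 2 or knockout 3, 22 without knockout 6, 58 without knockout 1 and 122 without control 5.

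Averaged over the 4 conditions, 142 genes rose and 30 fell in knockouts, of 18267 tested. Derl3 rose by 1.67 ± 0.28 log2 units (limma adjusted p = 0.000268; ENSMUSG00000009092, chromosome 10, 75893413 to 75895941), Osbpl3 by 1.13 ± 0.14 (adjusted p = 4.71e-07) and Adgrg2 by 1.01 ± 0.16 (adjusted p = 6.78e-05). Fam19a2 rose by 3.19 ± 0.44 (adjusted p = 5.86e-06), with a mean under 50 in fasted and refed livers. Among genes with a mean of at least 50 in each table, the other largest rises were those of Mup pseudogenes, at 1.41 ± 0.15 for Mup-ps16 (adjusted p = 3.7e-08) to 1.61 ± 0.21 for Mup-ps12, with Mup-ps3, Mup-ps8, Mup-ps11, Mup-ps14 and Mup-ps15 between 1.41 and 1.57. Genes that fell included Sdr9c7, a short-chain dehydrogenase (-0.63 ± 0.11, adjusted p = 0.000495) and Itih5, a hyaluronan-binding matrix protein (-0.51 ± 0.10, adjusted p = 0.00273). The list goes on with Raet1d, a ligand of an activating receptor of natural killer cells (-0.75 ± 0.18, adjusted p = 0.0206) and Hapln4 (-0.55 ± 0.12, adjusted p = 0.0111). Prim1, a DNA primase subunit (-0.47 ± 0.12, adjusted p = 0.047), the complement gene C6 (-0.39 ± 0.10, adjusted p = 0.0448) and Lhpp, a phosphatase (-0.38 ± 0.09, adjusted p = 0.0202), fell as well. Raet1d overlaps its paralog Raet1e on the same strand and Lhpp overlaps Fgfr2 on the opposite one, so their levels are uncertain. With no filter on low values Prim1 and C6 missed the threshold. Of the 142 genes that rose, 119 had the same sign in all 4 conditions, and of the 30 that fell, 30 did. These genes were called on the mean of the same 4 differences, which favours equal signs. The counts are therefore a description and no separate evidence that the conditions agree.

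Changes within each condition follow for Osbpl3 and Derl3 of the averaged comparison. In limma the direct tests given below called 0 genes as differing between diets or feeding states. Osbpl3 was at 1.11 ± 0.25 on ND (136 ± 42.9 to 296 ± 105 normalized counts), 0.07 ± 0.12 on CDAHFD (1750 ± 249 to 1840 ± 303), 1.56 ± 0.28 after fasting (153 ± 52.7 to 456 ± 187) and 1.79 ± 0.31 after refeeding. Of these the last alone passed within its condition. Derl3 was at 1.34 ± 0.52, 2.05 ± 0.39, 1.09 ± 0.65 and 2.18 ± 0.47 in the same order, and none of these passed within a condition over all genes. The unfolded protein response list as a whole had 24 of 26 members higher over the 4 conditions (camera adjusted p = 7.29e-09, adjusted p = 0.849 with an estimated correlation). Over all genes 1 rose, and 6 did when adjusted over the list alone, namely Derl3, Asns (0.81 ± 0.28), Psat1 (0.70 ± 0.22), Nupr1 (0.57 ± 0.17), Sesn2 (0.43 ± 0.13) and Dnajb9 (0.40 ± 0.12). The other members passed in neither way, among them Hspa5 (0.19 ± 0.13), Hsp90b1 (0.10 ± 0.09), Calr (0.01 ± 0.06) and Xbp1 (-0.05 ± 0.06). Interferon response genes were also higher as a list (camera adjusted p = 7.29e-09, adjusted p = 0.849 with an estimated correlation). Of 39 lists, 8 passed with the preset correlation and 0 with an estimated one. Cpt1a was at 0.14 ± 0.07 (limma adjusted p = 0.533). Of the genes tested, 1705 had an unadjusted p under 0.05, against 913 by chance. The count of 172 was 350 with weighted libraries and 270 by DESeq2.

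**Figure D2:**
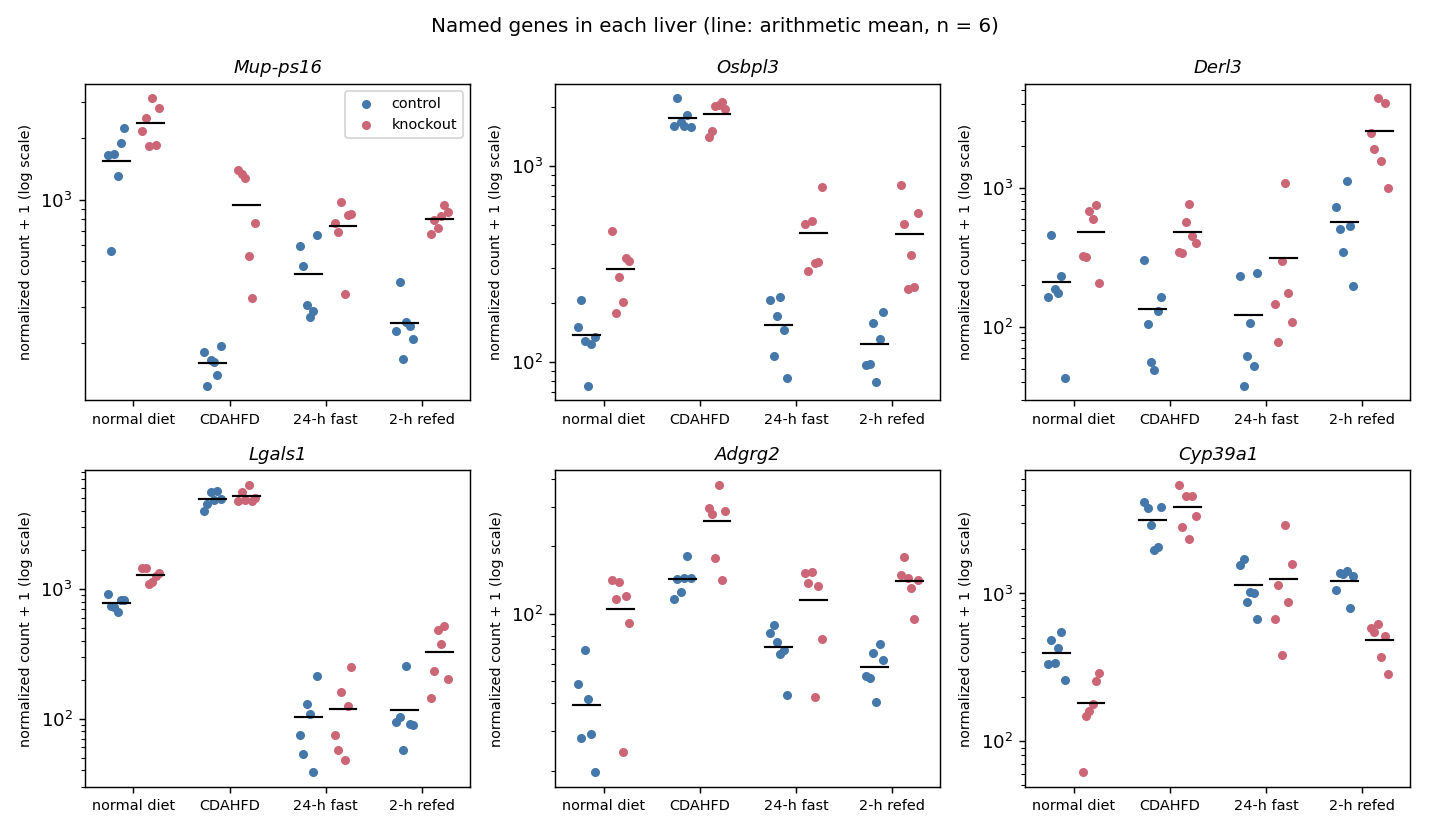
Normalized counts plus 1 (vertical axis, log scale) of Mup-ps16, Osbpl3, Derl3, Lgals1, Adgrg2 and Cyp39a1 in each liver, by condition and genotype; points are livers and lines mark the arithmetic mean, n = 6 per group. Mup-ps16 is higher in knockouts in all 4 conditions by 0.70 to 2.39 log2 units, and Osbpl3 shows no such gap on CDAHFD (0.07).

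**Figure D3:**
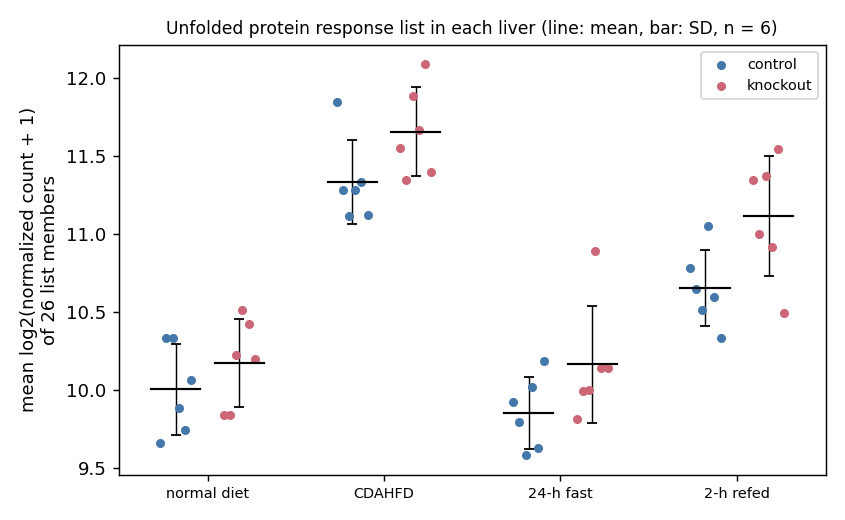
Mean log2(normalized count + 1) of 26 members of the unfolded protein response list in each liver (vertical axis) by condition and genotype (horizontal axis); points are livers, lines the group mean and bars its SD, n = 6 per group. Of the 26 members tested in all conditions, 24 were higher averaged over the 4 conditions.

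The Mup family was set out gene by gene because its pseudogenes recur among the changed genes. All tested members lie in the chromosome 4 cluster except Mup-ps22, a processed pseudogene on chromosome 11, which leaves 20 pseudogenes in the cluster, 16 of them higher. Of 21 tested Mup pseudogenes 14 rose over the 4 conditions and 17 were higher, while of 21 coding Mup genes 0 passed and 16 were higher. Those 16 lie together from Mup6 to Mup19, at 0.29 (Mup7) to 1.10 ± 0.30 (Mup8, limma adjusted p = 0.0585). Mup4 (-0.33) on one side and Mup5 (-0.27), Mup20 (-0.28), Mup3 (-0.22) and Mup21 (-0.04) on the other were lower. The lower pseudogenes, Mup-ps17, Mup-ps19, Mup-ps20 and Mup-ps21, also lie on that other side. The mean log2 change of all 21 tested pseudogenes, called or not, was 0.76 ± 0.41 on ND (exact permutation p = 0.0325), 1.58 ± 0.41 on CDAHFD (exact p = 0.00866), 0.24 ± 0.49 after fasting (exact p = 0.626) and 1.29 ± 0.26 after refeeding (exact p = 0.00216). The family was chosen after its genes were seen among the calls, so these p-values describe a hypothesis. Without control 2 the ND change was 0.38 ± 0.16 (exact p = 0.0584), and the exact p was also 0.05 or more without knockout 1, 2, 3, 5 or 6. The fasted change ranged from 0.02 without knockout 5 to 0.57 without control 6. The coding Mup genes were at 0.48 ± 0.49, 0.80 ± 0.54, -0.16 ± 0.49 and 0.55 ± 0.31 in the same order, with exact p = 0.452, 0.158, 0.723 and 0.113. Coding Mup genes took 8.35% ± 3.06 of all counts in ND controls and 10.45% ± 2.61 in ND knockouts (SD, n = 6), and 0.72% ± 0.17 and 0.91% ± 0.45 on CDAHFD. Mup-ps16 overlaps a processed transcript on its own strand, and reads were not separable between the copies.

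**Figure D4:**
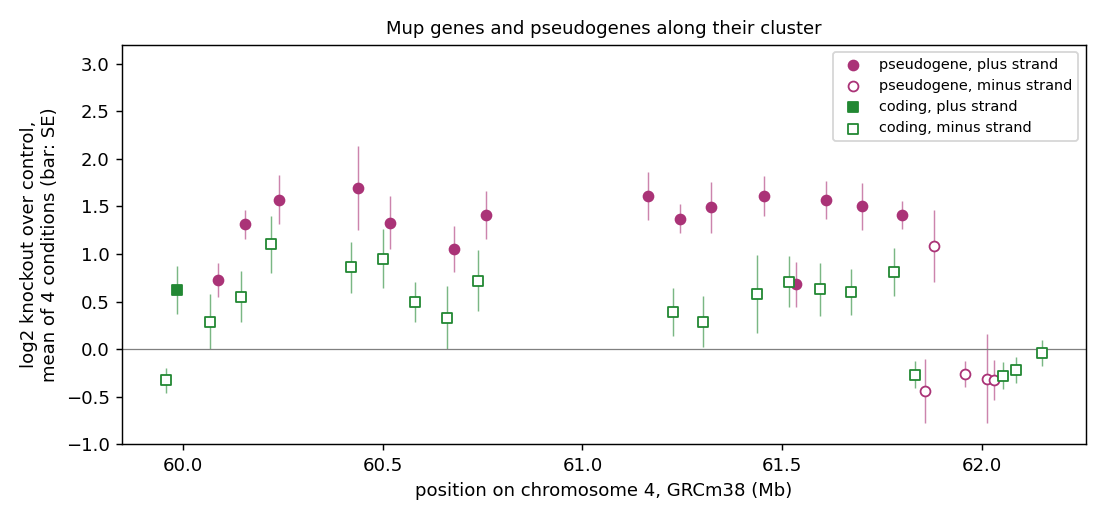
Log2 change, knockout minus control averaged over the 4 conditions (vertical axis, with SE), of Mup genes and pseudogenes by position on chromosome 4 (horizontal axis, GRCm38). Of the 20 pseudogenes shown 14 passed the test and of the 21 coding genes 0 did.

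Whether the genotype difference itself differed between diets or feeding states was tested directly. Between CDAHFD and ND, 0 genes passed in limma (970 of 18908 at an unadjusted p under 0.05, against 945 by chance, smallest adjusted p = 0.921). There edgeR called 0 and DESeq2 5. Between refeeding and fasting, 0 passed in limma (1500 of 18744, against 937 by chance, smallest adjusted p = 0.2). Here edgeR called 0 and DESeq2 2. For Osbpl3 the change on CDAHFD minus that on ND was -1.04 ± 0.29 (adjusted p = 0.921), for Lgals1 -0.63 ± 0.14 (adjusted p = 0.921) and for Mup-ps16 1.68 ± 0.46 (adjusted p = 0.921). On simulated interactions the test recovered 68.7% of genes changed 2-fold between the diets and 64.2% between the feeding states, over 18736 and 18575 genes. The simulated genes varied independently, so the real recovery may be lower.

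Calls were shared between CDAHFD and refeeding. Mup-ps2, Mup-ps10, Mup-ps12, Mup-ps14, Mup-ps16 and the predicted gene Gm21286, which also lies in the Mup cluster, rose in both: 6 genes, against 0.029 from independent lists of 22 and 25 among 18863 genes. All 6 lie in 1 cluster of near-identical copies, so they are not 6 independent genes and that expectation does not apply to them. No gene was called in both tables of any other pair of conditions. Across genes, which are not independent replicates, the log2 changes of ND and refed knockouts had Pearson's r = 0.279 and Spearman's rho = 0.203. Those of CDAHFD and refed knockouts had 0.173 and 0.089, and those of fasted and refed knockouts 0.015 and -0.054, as a description without a test. For ND and fasted knockouts the values were 0.209 and 0.173, for ND and CDAHFD 0.115 and 0.041, and for CDAHFD and fasted 0.01 and -0.097.

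Levels in the controls were set side by side across conditions as ppm of each library's counts. The tables were normalized separately and condition coincides with the table, so no test was run. On CDAHFD the median member was higher than on ND by 4.41 log2 units for the 16 macrophage markers, 4.01 for the 11 cholangiocyte markers, 3.66 for the 30 fibrosis genes and 3.16 for the 25 cell cycle genes, and all of these members were higher. The 17 male-biased genes were lower on CDAHFD, with a median of -2.40. Trem2, a marker of macrophages in fatty liver, was at 0.444 ± 0.0955 ppm in ND controls and 68 ± 17 in CDAHFD controls (SD, n = 6). Col1a1, the main fibrillar collagen, was at 1.72 ± 0.666 and 123 ± 52.5. After refeeding, 2 of 17 gluconeogenesis genes were higher than after fasting, with a median of -1.06. Of the others, 18 of 18 heat shock genes were higher (0.87) and 22 of 24 cholesterol genes were higher (0.53). Pck1, an enzyme of gluconeogenesis, was at 3330 ± 696 ppm in fasted and 634 ± 901 in refed controls. The refed value is carried by 1 liver at 2460, without which the mean was 270. Trem2, Col1a1 and Pck1 were chosen after their values were seen. Cpt1a was at 221 ± 35.6, 330 ± 38.8, 659 ± 68.9 and 420 ± 56.8 ppm in the controls on ND, on CDAHFD, after fasting and after refeeding. Ccl2 was at 0.377 ± 0.222, 7.44 ± 1.96, 0.0524 ± 0.0507 and 0.177 ± 0.131.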

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

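For the Mup pseudogenes, the 3 tests of an explanation were chosen only after the result was seen.

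A value was singled out where 1 liver of a group of 6 stood far from the other 5. This held for 16 of 194 groups of values, where chance gives about 10, or 1 in 20. The values of 15 of them follow. In ND control 2, 6 Mup pseudogenes were the lowest of their group: Mup-ps12 at 55.4 normalized counts (others 308 to 575), Mup-ps14 at 73.3 (348 to 551), Mup-ps3 at 107 (761 to 1060), Mup-ps15 at 144 (969 to 1270), Mup-ps11 at 90.3 (738 to 1110) and Mup-ps8 at 159 (1090 to 1410). In fasted control 6, Mup-ps3 was highest at 1210 (others 103 to 256) and so was Mup-ps15 at 1320 (135 to 311). In fasted knockout 4, Mup-ps16 was lowest at 345 (others 695 to 972).

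The mean rise of all 21 tested Mup pseudogenes over the 4 conditions was 0.97 ± 0.20 log2 units, in a family chosen because some of its genes were called. All tested pseudogenes together rose by 0.55 ± 0.08 more than the coding Mup genes (permutation p = 1e-05, the smallest the draws can give). This comparison was chosen after 14 pseudogenes and 0 coding genes had been called, which favours such a difference. How reads matching several places were counted is not given, so shared reads need not give equal changes. Reads shared with the coding genes, as the whole cause or in part, or among the pseudogenes, therefore stay open. A rise of all male-biased growth hormone targets by as much is argued against. The median change of 14 such genes outside the Mup family was -0.04 with an SD of 0.19, and their score difference was -0.044 ± 0.09. A much smaller general rise stays open. The control livers named above weigh on single conditions, as the ND change of all 21 was 0.76 and came to 0.38 ± 0.16 without control 2, while the difference from the coding genes stayed at 0.52 to 0.58 without any 1 library. An effect of genotype on this family may remain as a hypothesis, and sequence differences between mice at the cluster were not tested.

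Foxk2 was highest in ND control 3 at 1040 normalized counts (others 749 to 840). Itih5 was highest in ND knockout 2 at 659 (others 480 to 516). Total reads were highest in CDAHFD knockout 6 at 83.8 M (others 41 M to 53.1 M). Lhpp was lowest in fasted knockout 6 at 2350 normalized counts (others 3330 to 3810). Gins2 was lowest in refed control 5 at 362 (others 433 to 470). C6 was lowest in refed control 2 at 2720 (others 3490 to 4040). Of the named genes, 0 separated the genotypes in opposite directions in 2 conditions.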

How the results depend on the processing

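The permutation test of list scores was chosen only after the result was seen. The direction of the counts was kept: rises outnumbered falls in CDAHFD, refed and averaged knockouts under each alternative run. With a library left out, the calls of named genes were not followed one by one. Under all the other alternatives 42 calls of named genes kept their sign. Of these calls 0 were lost with a pseudocount of 0.5, a mean of at least 50, TMM or DESeq2. The losses were 1 with a pseudocount of 10 (Prim1), 1 with edgeR (C6), 2 with weighted libraries (G0s2 and C6), 3 without a filter (Osbpl3, Prim1 and C6) and 4 in ppm (Cldn14, Gse1, Gins2 and Prim1). With weighted libraries the counts were 7 genes on ND, 65 on CDAHFD, 99 after refeeding, 350 over the 4 conditions and 1 for refeeding against fasting. The main counts were 1, 25, 36, 172 and 0. DESeq2 called 24, 147, 11 (fasted, main count 0), 230 and 270 genes, 5 for the difference between diets and 2 for that between feeding states, where no filter gave 1. With the replicate number as a replicate block the counts were 17 on ND, 38 on CDAHFD, 43 after refeeding, 280 over the 4 conditions and 4 for the feeding states, and 5 named calls were lost, among them Osbpl3, G0s2, Gse1 and Gins2. The labels give the numbers no meaning, and 3, 4, 4 and 2 of the 6 same-numbered pairs (ND, CDAHFD, fasted, refed) had a correlation above 0.1, so the livers were treated as sharing only a number. As a hint from the data that some numbers may be shared, the mean correlation was 0.11, 0.12, 0.24 and 0.01 for the same number against -0.02, -0.02, -0.05 and 0 for others. In the same order, 3, 3, 4 and 1 of 6 controls and 3, 2, 3 and 1 of 6 knockouts correlated best with their own number. Numbers without meaning would give about 1 of 6, so a shared factor stays open on ND, on CDAHFD and after fasting. The main tests, the permutations and the splits did not take it into account. Gene lists past the threshold went from 12, 18, 21 and 12 to 0 in each condition with an estimated correlation and to 0 in each with the test of list scores. Camera's preset correlation of 0.01 lies below the median estimate of 0.2 to 0.385. At an adjusted p under 0.1, shared calls were 1 for ND and CDAHFD, 1 for ND and refeeding and 10 for CDAHFD and refeeding, against 0, 0 and 6. Leaving out 1 library at a time gave 0 to 3 genes on ND, 10 to 44 on CDAHFD, 0 after fasting, 13 to 122 after refeeding (the highest without control 5) and 139 to 190 over the 4 conditions. Foxk1 ranged from -0.333 to -0.195 on ND, from -0.278 to -0.127 on CDAHFD, from -0.397 to -0.334 after fasting and from -0.329 to -0.208 after refeeding. Values near 0 turned sign: Cpt1a after refeeding was 0.04 by edgeR and 0.04 by DESeq2 against -0.01. Foxk2 after refeeding (-0.013) ranged from -0.115 to 0.048. It was 0.048, 0.002, 0.022 and 0 without controls 2, 3, 4 and 6 and 0.004 and 0.039 without knockouts 1 and 6. No library stood apart in correlation, so the setting without such libraries was not run. For all these shifts the cause was not tested.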

Other observations

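The tests of list scores, of the shares of cell types, of both explanations for the CDAHFD lists and of windows along the chromosomes were chosen only after the result was seen, and the genes of the next 2 paragraphs were chosen after their values were seen.

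Over the 4 conditions, several genes of autophagy, the digestion of the cell's own parts, rose in knockouts. They were Atg13, which starts the process, by 0.33 ± 0.05 log2 units (limma adjusted p = 0.000117), and Wdr45 by 0.24 ± 0.05 (adjusted p = 0.00496). The mitophagy receptor gene Bnip3l rose by 0.23 ± 0.06 (adjusted p = 0.0415) and Wipi2 by 0.15 ± 0.04 (adjusted p = 0.0202). The autophagy and lysosome list as a whole was not set apart (score difference 0.038, permutation p = 0.13, camera adjusted p = 0.277). Bnip3l has a called pseudogene, Bnip3l-ps (0.23 ± 0.06), and sharing of reads between them was not tested. Wipi2 lies near Foxk1. Adrb3, the beta-3 adrenergic receptor, had the smallest adjusted p of all genes (0.90 ± 0.09, adjusted p = 5.29e-09). Cd36 (0.57 ± 0.08, adjusted p = 5.5e-06), Ifi27 (0.52 ± 0.07, adjusted p = 2.57e-06) and the secreted protein gene Fetub (0.49 ± 0.06, adjusted p = 1.47e-06) rose as well. Trf fell by 0.33 ± 0.06 (adjusted p = 0.00273) and Ezh2, a histone methyltransferase, by 0.36 ± 0.07 (adjusted p = 0.00349).

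The noncoding RNA genes Meg3 (1.03 ± 0.27, adjusted p = 0.0448), Rian (1.04 ± 0.25, adjusted p = 0.0236) and Dio3os (1.17 ± 0.27, adjusted p = 0.0156), which lie in 1 imprinted region of chromosome 12 between 109541001 and 110278172, each rose in limma. Their rise as a group was not tested, and no window of chromosome 12 passed the test described below. In CDAHFD knockouts the neutrophil granule genes Ngp (-2 ± 0.68) and Camp (-1.39 ± 0.39) fell when adjusted over the neutrophil list alone, and not over all genes (adjusted p = 0.484 and 0.339).

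Genes called over the 4 conditions lay together more often than chance in 3 of 1658 windows of 1 Mb. In 2 of them, on chromosome 4 from 60000001 to 61000000 and from 61000001 to 62000000, 8 of 18 and 8 of 20 tested genes were called (hypergeometric adjusted p = 3.39e-09 and 4.8e-09). These were Mup pseudogenes and 2 predicted genes, Gm21286 and Gm13775. The other, on chromosome 3 from 96000001 to 97000000, held 5 of 44 (adjusted p = 0.0305), among them the histone genes Hist2h2aa1, Hist2h2aa2 and Hist2h2ac. Clusters of neighbouring genes changing together is a hypothesis that this result may favour, but both clusters hold near-identical copies, for which reads shared between copies would give the same picture. Near Foxk1 itself, 5 of 267 genes within 10 Mb were called (1.87%) against 166 of 17999 elsewhere (0.922%, Fisher's exact p = 0.106), so sequence carried along with the floxed allele could be neither shown nor excluded.

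The unfolded protein response list had a score difference of 0.315 ± 0.087 over the 4 conditions (permutation p = 0.00062, 0.0242 adjusted over 39 lists), the 1 list past that test, but did not pass camera with an estimated correlation (adjusted p = 0.849). The adjustment covers this comparison alone, while list scores were also tested in each condition and between diets and feeding states. The score difference was 0.17 on ND (4 of 6 knockouts above the control mean), 0.32 on CDAHFD (6 of 6), 0.31 after fasting (5 of 6) and 0.46 after refeeding (5 of 6). That 1 library decides it is argued against, since without any single library the score stayed at 0.279 to 0.346 and the highest permutation p was 0.00123. A lower share of hepatocyte RNA stays open, as stellate (0.13 ± 0.078), Kupffer (0.094 ± 0.11), macrophage (0.037 ± 0.074) and endothelial markers (-0.047 ± 0.036) spanned a gap of 0.177 with a permutation p of 0.415.

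In CDAHFD knockouts the macrophage, cholangiocyte, fibrosis and cell cycle lists were lower together, with a mean score difference of -0.364 ± 0.195 (exact permutation p = 0.0887). Livers that differ in the course of the disease whatever their genotype could give this. The genotypes were not separated, but the 4 list scores had a mean correlation of 0.44 among the 6 controls, below the 0.5 set for that explanation. That mean takes in the cell cycle list, whose lowest control was control 6 (8.19). Control 1 was lowest and control 5 highest for the macrophage (11.55 and 12.19), cholangiocyte (7.99 and 9.55) and fibrosis scores (10.02 and 11.03). The mean therefore does not argue against that explanation for these lists. Knockout 3, which correlated least with its group, accounts for part: without it 69.1% of the difference was left (-0.251 ± 0.173, exact p = 0.182), with the cell cycle list going from -0.358 to -0.424 while macrophage (-0.319 to -0.175), cholangiocyte (-0.54 to -0.3) and fibrosis (-0.24 to -0.106) shrank. Neither explanation nor an effect of genotype on the disease can be excluded with these 12 livers.

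Chance assignment of livers to groups was checked by counting again under other splits of the same livers, 100 per result with the real one included. The shares are not adjusted over the 11 results, and with 100 splits none can fall below 1 in 100. They therefore exclude chance for no result. They argue against it for the 172 genes over the 4 conditions (1 split as large, highest other 67). For the 25 genes on CDAHFD the share was as small (1 split), with a highest other of 18. For the 36 genes after refeeding the share was small too (2 splits), though another split called more (highest other 83). The 21 lists after fasting also had a small share (3 splits, highest other 24), but 0 passed with an estimated correlation or the test of list scores. That count is left open. Chance is not argued against for the 1 gene on ND (11 splits, highest other 35), the 12 lists on ND (53 splits, highest other 20), the 18 lists on CDAHFD (49 splits, highest other 30) or the 12 lists after refeeding (41 splits, highest other 20). For the counts of 0 after fasting (highest other 0), between diets (highest other 151) and between feeding states (highest other 786), 100 of 100 splits are as large by construction, so the splits say nothing about chance there. Single splits called many genes where the real one called 1 (35 on ND) or 0 (151 and 786 in the tests of a difference). The median of the other splits was 0 in each, and 10 (ND), 10 (diets) and 4 (feeding states) of them called any gene. The cause was not tested. Other splits gave a median of 10 to 17 lists, so camera with its preset correlation passed about as many lists on ND, on CDAHFD and after refeeding when genotype was mixed.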
